A study of Mus musculus with 12 samples.

How the data were processed

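RNA of bone marrow KSL cells from 10-week-old C57Bl/6 mice was isolated after sorting and labelled with biotin by an Ovation kit, per the labels' protocols. The 12 arrays fall into 6 of non-irradiated mice and 6 of mice given 550 cGy from a cesium irradiator. The series' design text places the isolation at day 14 and also names committed progenitors, which were not analysed here.

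The values deposited by the authors are log2 expression values with 1 row per probe set. Partek is named in the submitters' processing notes. Its version and role, and the background correction and normalization, are not given in the sources used here. The array medians differ by less than 0.1. The value table used here holds no control probe sets. A second table deposited by the authors gives a gene symbol, an unadjusted p-value, a linear ratio of 550 cGy over 0 cGy and a signed fold for each changed probe set. Per the file headers it also gives the authors' F statistic and sums of squares, scores of an analysis of variance. The ratios and p-values were recomputed from the log2 values to check scale and direction. The log2 ratios differed by at most 2.36e-05, and p by at most 0.000499 of its value.

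Only the second table pairs probe sets with genes. Of its probe sets, 436 name 1 gene and 18 name several or none and stay unnamed. Symbols were updated through the gene ID with a RefSeq gene table (GRCm38.p6), which matched 425 and changed 21. The brightest named probe set by the mean over 12 arrays stands for its gene, and no gene had named probe sets of opposite direction. Probe sets of these genes outside the authors' table carry no name here, so they could neither stand for the gene nor be compared in direction.

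Probe sets were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default prior), with 1 coefficient for irradiated against non-irradiated arrays, all 12 arrays and no filter on dim probe sets. P-values were adjusted by the Benjamini-Hochberg method over all probe sets and called under 0.05. Single values were compared by exact permutation tests. Within a replicate set, 3 against 3 arrays cannot give a two-sided p below 0.1. The fit was tested on simulated data with 200 changed among 22626 probe sets. It recovered 71 of 100 changed by 1 and 32 of 100 changed by 0.5 on the log2 scale, and called 5 unchanged ones. The simulated noise was independent between probe sets and arrays, without replicate sets, and far fewer probe sets changed than the 2567 called in the data. These rates check the fit and do not carry over to the data.

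A test of genes was intended, with camera for 31 gene lists against all other genes. Without names for most probe sets, probe sets were tested in place of genes and camera was not run. In its place, chosen after the data were seen, list members in the authors' table were counted by direction. The 4 lists with at least 5 of them were compared with the other named genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment. This test takes genes as independent, and its p is too small where they vary together. The named genes number 128 higher and 197 lower. The lists, the main test, the rule for named genes and the alternatives other than those on replicate sets were fixed before the data were examined. The lists covered stem cell, lymphoid, granulocyte-monocyte, erythroid, megakaryocyte, cell cycle, DNA damage, inflammatory, signalling and metabolic genes and markers of other bone marrow cells.

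The rule named Grb10, Kit, Ly6a and Cdkn1a, then the 10 largest rises and 10 largest falls past the threshold whose irradiated arrays all lay above or all below the controls. Such separation held for 5.80% of probe sets, against 0.216% by chance. Its last part, on lists called by camera, was replaced after the data were seen by up to 4 called genes with the smallest p from each list with at least 3 genes in the table. Other list members were named after their values were seen. Results for 3 list members are not reported here, though they count in the totals and means of their lists.

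No pair of the 12 arrays held identical values, and the smallest SD of the difference between 2 arrays was 0.28, so all were kept. The labels name no batch. Replicates 1 to 3 and 4 to 6 were added as a term and as separate fits after the data were seen. Other alternatives were leaving out the dimmest 40% of probe sets, quantile normalization, subtraction of array medians, a trended and robust prior, array weights, a replicate block and leaving out each array in turn. List tests used SciPy 1.17.1 and figures matplotlib 3.10.9.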

Results

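Gene expression was measured by array in bone marrow KSL cells of C57Bl/6 mice, in 6 arrays of non-irradiated cells (0 cGy) and 6 arrays of cells from mice given 550 cGy. KSL cells are sorted as positive for Kit and Sca-1 and negative for lineage markers, and hold the hematopoietic stem cells and early progenitors. The comparison addresses how regenerating stem and progenitor cells, taken at day 14 after irradiation, differ from those at steady state. Each array gave log2 values for 22626 probe sets, and the array medians lay between 6.94 and 7.01. The number of arrays limits the precision, and the median SE of a log2 difference between the groups was 0.132. The labels do not say that the arrays came from separate mice, so the p-values measure the spread between these samples, which may be technical. Gene names came from the authors' deposited table of changed probe sets. The 325 genes with a name were thus selected by the authors on these same arrays, and other genes were not identified here.

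After irradiation the KSL cells had lower levels of the lymphoid-priming genes identified, with Dntt 6.07-fold and Flt3 4.19-fold lower. The erythroid genes identified were higher, with Klf1 6.92-fold and Gata1 3.06-fold higher. Grb10, an imprinted adaptor gene, was 2.07-fold to 3.34-fold higher depending on the named probe set. The chemokine genes Ccl3 and Ccl4 were 6.80-fold and 4.79-fold lower. Across all probe sets, 1329 were higher and 1238 lower in limma at a Benjamini-Hochberg adjusted p under 0.05, or 11.3% of those tested. Of these, 156 were at least 2-fold higher and 254 at least 2-fold lower. With the median of each array subtracted, 1765 were higher and 1081 lower, so that 62.0% of the calls were rises, against 51.8% in the deposited values. The count of higher probe sets was 740 without irradiated replicate 1, 769 without irradiated replicate 6, 830 without irradiated replicate 5 and 837 without control replicate 1, and that of lower ones was 773 without irradiated replicate 1.

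The groups separated along principal component 1, which held 35.8% of the variance, by 51.1 units (exact permutation test, two-sided p = 0.002165, the smallest possible for 6 against 6 arrays). Replicates 1 to 3 differed from replicates 4 to 6 along component 2, with 16.5% of the variance. The control arrays 1 to 3 lay at -51.52 to -40.99 on component 1 and the control arrays 4 to 6 at -9.84 to 0.02, and the irradiated arrays at 12.09 to 34.53. Values within each of these replicate sets, which were chosen after the data were seen, are therefore given beside the pooled ones for Grb10, list means and some other genes. Of 50 named genes other than Grb10, 10 lost the call in replicates 1 to 3 alone, among them Hspa1b, Slamf1, Selp, Ccne1 and Egr2. In replicates 4 to 6 alone, 3 lost it. With the replicate set as a term, 2099 probe sets were higher and 1833 lower, and they included all 2567 pooled calls. Replicates 1 to 3 alone gave 539 higher and 601 lower probe sets, replicates 4 to 6 alone 720 and 738. All 376 probe sets called in both had the same direction.

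**Figure D1:**
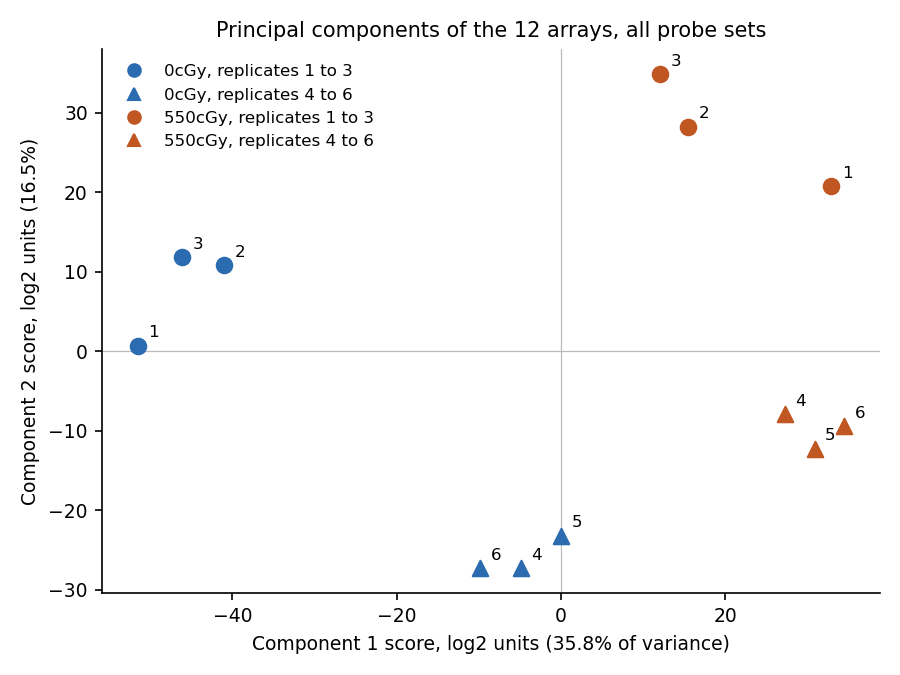
Scores of the 12 arrays on principal components 1 and 2 of the log2 values (both axes in log2 units), non-irradiated in blue and irradiated in orange, with circles for replicates 1 to 3, triangles for replicates 4 to 6 and the replicate number beside each point. The irradiated arrays lie at 12.09 to 34.53 on component 1 and the control arrays at -51.52 to 0.02, and component 2 separates the replicate sets within each group.

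Grb10 encodes an adaptor protein that binds activated receptor tyrosine kinases, and it rose in its 3 named probe sets. The brightest went from 7.45 ± 0.15 to 8.50 ± 0.47 (log2, mean ± SD, n = 6 per group), a log2 change of 1.05 (SE 0.18, limma adjusted p = 0.00494). The probe set with the largest change went from 6.94 ± 0.24 to 8.68 ± 0.30, a change of 1.74 (SE 0.15, adjusted p = 6.30e-05). The dimmest went from 6.21 ± 0.60 to 7.56 ± 0.55, a change of 1.35 (SE 0.30, adjusted p = 0.0139). In each of them all 6 irradiated arrays lay above all 6 control arrays (exact permutation test, two-sided p = 0.002165). These probe sets carry a name because they changed at least 2-fold on these arrays, so this p is not independent evidence. Any Grb10 probe set that changed less would have no name here. The change of the brightest was 0.96 in replicates 1 to 3, where it missed the threshold (adjusted p = 0.128), and 1.14 in replicates 4 to 6 (adjusted p = 0.00854). Kit and Ly6a, which encode the sorting markers Kit and Sca-1, had no named probe set.

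The largest rises among genes with no overlap between the groups were those of Ahsp, which encodes a chaperone of alpha-hemoglobin (7.52-fold), Klf1, an erythroid transcription factor (6.92-fold), Hspa1b, an inducible heat shock protein (5.50-fold, with an adjusted p of 0.0619 in the dimmest of its probe sets), and Mt1, a metallothionein (5.31-fold). Tjp1, a tight junction scaffold, rose 5.12-fold (log2 change 2.36, SE 0.12, adjusted p = 1.43e-06), followed by Epdr1 (4.80-fold), Bex4 (3.89-fold), Socs2, a suppressor of cytokine signalling (3.82-fold), Gdf3, a ligand of the TGF-beta family (3.76-fold), and Podxl, a sialomucin (3.75-fold). The largest falls were those of Wfdc18 (7.47-fold), Ccl3 (6.80-fold), Dntt (6.07-fold), Ccl4 (4.79-fold) and Satb1 (4.40-fold). Lif, a cytokine (4.30-fold), Serpinf1, a secreted serpin (4.26-fold), Flt3 (4.19-fold), Sdc4, a cell surface proteoglycan (4.01-fold), and Nr4a3, a nuclear receptor (3.73-fold), followed. The adjusted p of these 20 genes lay between 1.43e-06 and 0.0125.

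**Figure D2:**
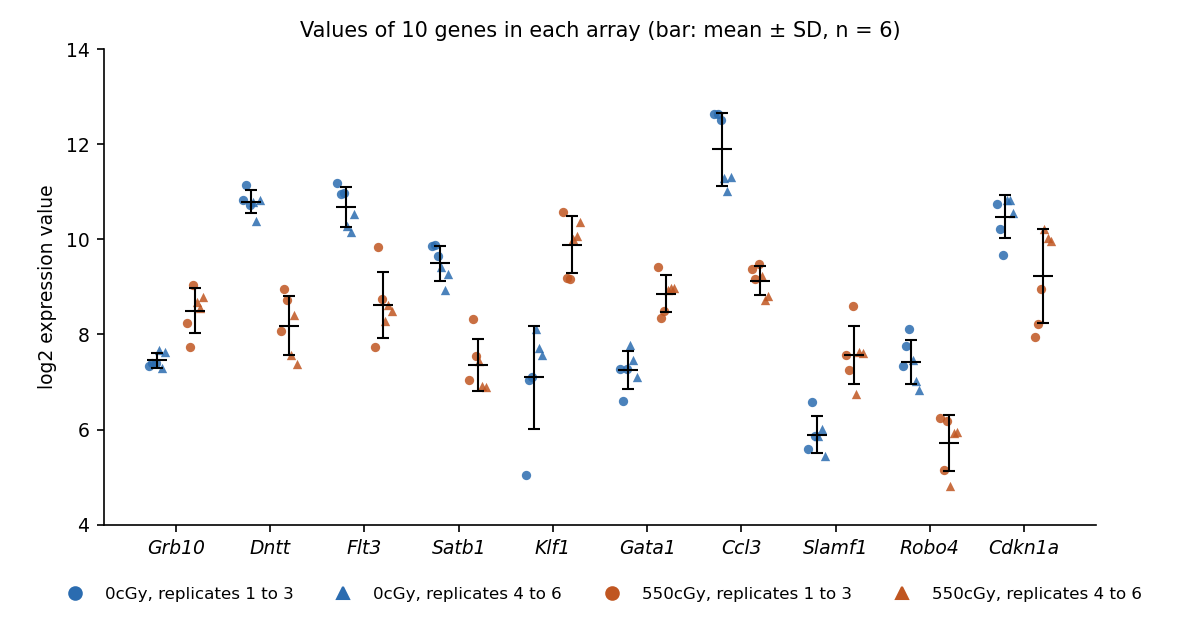
Log2 expression values (y axis) of 10 genes (x axis) in each array, non-irradiated in blue and irradiated in orange, with circles for replicates 1 to 3, triangles for replicates 4 to 6 and black bars for the mean ± SD of 6 arrays. Grb10, Klf1, Gata1 and Slamf1 were higher and Dntt, Flt3, Satb1, Ccl3 and Robo4 lower in all irradiated arrays than in all control arrays, while the arrays of Cdkn1a overlapped.

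The lymphoid-priming genes of the authors' table fell. Of the 22 genes of the list, 9 were in the table, and all 9 fell. Dntt, the terminal transferase of early lymphoid cells, went from 10.79 ± 0.24 to 8.19 ± 0.63 (log2 change -2.60, SE 0.25, adjusted p = 0.000148). Satb1, a chromatin organizer of lymphoid cells, changed by -2.14 (SE 0.24) and Flt3, a cytokine receptor of multipotent and lymphoid progenitors, by -2.07 (SE 0.29). Notch1, Lsp1, Runx2, Sox4, Cd52 and Ccr9 were 2.41-fold, 2.37-fold, 2.27-fold, 2.17-fold, 2.12-fold and 2.08-fold lower. The split of 0 rises and 9 falls differed from that of the other named genes (Fisher's exact test, two-sided p = 0.0133, adjusted p = 0.0177 over 4 lists). Joint variation of these genes, which would make this p too small, was not measured. Adjusted over the list alone, 9 passed. That outcome was fixed in advance for this and every other list, because the table holds only probe sets with an unadjusted p under 0.05 on these arrays. The mean log2 value of these genes differed by -1.70 in replicates 1 to 3 and by -1.35 in replicates 4 to 6.

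The erythroid genes of the table rose. Of the 27 genes of the list, 15 were in the table, all of them with higher means, and 12 rose past the threshold. Klf1 went from 7.10 ± 1.09 to 9.89 ± 0.60 (adjusted p = 0.00295) and Gata1, a transcription factor of erythroid and megakaryocytic cells, from 7.25 ± 0.40 to 8.86 ± 0.38 (adjusted p = 0.000784). Rhag, of the Rh complex, was 3.57-fold higher and Epor, the erythropoietin receptor, 3.51-fold. Mt2, a metallothionein that is not specific to red cells, was in this list too and was 7.06-fold higher. Ank1, Ermap and Tfrc had ratios of 2.86, 3.54 and 2.17 at adjusted p of 0.0899, 0.0511 and 0.0596 in their brightest probe set. The other probe sets of Ank1 (4.19-fold and 3.05-fold) and of Tfrc (2.08-fold) passed, at adjusted p of 0.00195, 0.00311 and 0.0105. The split of 15 higher and 0 lower genes differed from that of the other named genes (Fisher's exact test, two-sided p = 5.03e-07, adjusted p = 2.01e-06), but these genes varied together within the groups, with a mean pairwise correlation of 0.6372, so this p is too small by an unknown amount. Adjusted over the list alone 15 passed, which was again fixed by the selection of the table on these arrays. In the fit with the replicate set as a term 15 passed. The mean of the 15 genes differed by 1.96 in replicates 1 to 3 and by 1.69 in replicates 4 to 6, with control means of 6.64 and 7.75. The 5 globin probe sets of the table, of which 4 name several globin genes each, are not counted in the list. All 5 were higher, by 2.28-fold to 9.16-fold (adjusted p = 0.000588 to 0.00749), among them Hbb-b2, the gene named alone (3.04-fold). Of the heme synthesis genes, Cpox (2.62-fold) and Alad (2.17-fold) rose.

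Genes of long-term stem cells moved in both directions. Of 30 genes, 8 were in the table, and 3 rose and 5 fell, a split that did not differ detectably from that of the other named genes (Fisher's exact test, two-sided p = 1.0). Slamf1, which encodes the surface marker CD150, went from 5.89 ± 0.39 to 7.57 ± 0.61 (adjusted p = 0.00271), and Vwf, a marker of platelet-biased stem cells, and Gfi1b, a transcriptional repressor, were 2.20-fold and 2.09-fold higher. Robo4, a guidance receptor, was 3.27-fold lower, Hlf, a stem cell transcription factor, 2.36-fold, Ndn, an imprinted gene, 2.16-fold and Procr, which encodes the surface marker EPCR, 2.02-fold. The mean of the 8 genes differed by -0.57 in replicates 1 to 3 and by -0.10 in replicates 4 to 6. That 8 passed when adjusted over the list alone was fixed by the selection of the table. Vwf (adjusted p = 0.0282) lost its call without control replicate 2 or irradiated replicate 3, 4, 5 or 6, at adjusted p of 0.0512 to 0.0623. Of the megakaryocyte genes, Selp, which encodes P-selectin, rose (3.24-fold), as did Vwf, and Plek, a substrate of protein kinase C in platelets, fell (2.41-fold).

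Few cell cycle genes were in the table, and neither the DNA replication nor the mitosis list was tested for direction. All 4 of 42 DNA replication genes that were in the table rose, with Ccne1, a cyclin of S phase entry, 2.77-fold, Orc1, of the origin recognition complex, 2.58-fold, Mcm10, a replication factor, 2.41-fold and Rrm2, of ribonucleotide reductase, 2.23-fold higher. So did all 3 of 40 mitosis genes, the kinase genes Plk1 (2.23-fold) and Ttk (2.13-fold) and the hyaluronan receptor gene Hmmr (2.04-fold). The means of these lists differed by 1.69 and 1.44 in replicates 1 to 3 and by 0.94 and 0.74 in replicates 4 to 6. Of 19 inhibitor and quiescence genes, 3 were in the table, and Btg1 fell (2.36-fold). Cdkn1a, which encodes the inhibitor p21, went from 10.47 ± 0.46 to 9.22 ± 0.99 (log2 change -1.25, SE 0.39) and missed the threshold at an adjusted p of 0.0573, with 0.00633 under the replicate set term and 0.00633 to 0.110 over all alternatives. Btg2, an antiproliferative gene, had a log2 change of -1.12 (adjusted p = 0.0976, or 0.00366 with the set term). That change was -1.75 in replicates 1 to 3 and -0.49 in replicates 4 to 6, a difference with a limma adjusted p of 0.0364. In the other Btg2 probe set the changes were -1.96 and -0.13 (adjusted p of their difference 0.0401). The set term assumes the same change in both sets, which these values go against. Of 31 p53 target genes, 4 were in the table, and Trp53inp1 fell (2.09-fold, adjusted p = 0.0247), a call that ended without control replicate 1 or 2 or irradiated replicate 1, at 0.0514 to 0.0562. The others were Cdkn1a, Btg2 and Plk2, whose log2 change was -1.41 (adjusted p = 0.0538, or 0.0202 with the set term). For Plk2 the change was -2.48 in replicates 1 to 3 and -0.33 in replicates 4 to 6. The mean of the p53 target genes differed by -1.86 and -0.56 in the replicate sets, and that of the inhibitor genes by -1.74 and -0.67. Adjusted over the list alone, 4 replication, 3 mitosis, 3 inhibitor and 4 p53 target genes passed, which was fixed by the selection of the table.

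The immediate early genes of the table were lower. Of 24 immediate early genes, which respond quickly to growth factors and to cell handling, 10 were in the table, all with lower means, and 8 fell past the threshold, which Btg2 and Nr4a2 missed. Nr4a3 and Nr4a1, orphan nuclear receptors, changed by -1.90 (SE 0.38) and -1.52 (SE 0.29), and Egr3, a zinc finger transcription factor, by -1.06 (SE 0.11). Klf4, Egr1, Egr2, Klf2 and Ier3 were 2.35-fold, 2.23-fold, 2.23-fold, 2.13-fold and 2.07-fold lower. Nr4a2 had a log2 change of -1.27 (adjusted p = 0.110), being -2.73 in replicates 1 to 3 and 0.18 in replicates 4 to 6. The split of 0 higher and 10 lower genes differed from that of the other named genes (Fisher's exact test, two-sided p = 0.00737, adjusted p = 0.0147). This p takes the genes as independent, and how far they varied together was not measured. That 10 passed when adjusted over the list alone was fixed by the selection of the table. The mean of the list differed by -1.75 in replicates 1 to 3 and by -0.76 in replicates 4 to 6. Of 21 NF-kB inflammatory genes, 3 were in the table and fell, too few for the test of direction. Ccl3 went from 11.90 ± 0.77 to 9.13 ± 0.30 (adjusted p = 0.000312), Ccl4 from 10.79 ± 1.02 to 8.53 ± 0.38 (adjusted p = 0.00474), and Nfkbiz, a nuclear IkB protein, was 2.55-fold lower. The mean of these 3 genes differed by -2.79 and -1.46 in the replicate sets, and 3 passed when adjusted over the list alone, as the selection of the table made certain.

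**Figure D3:**
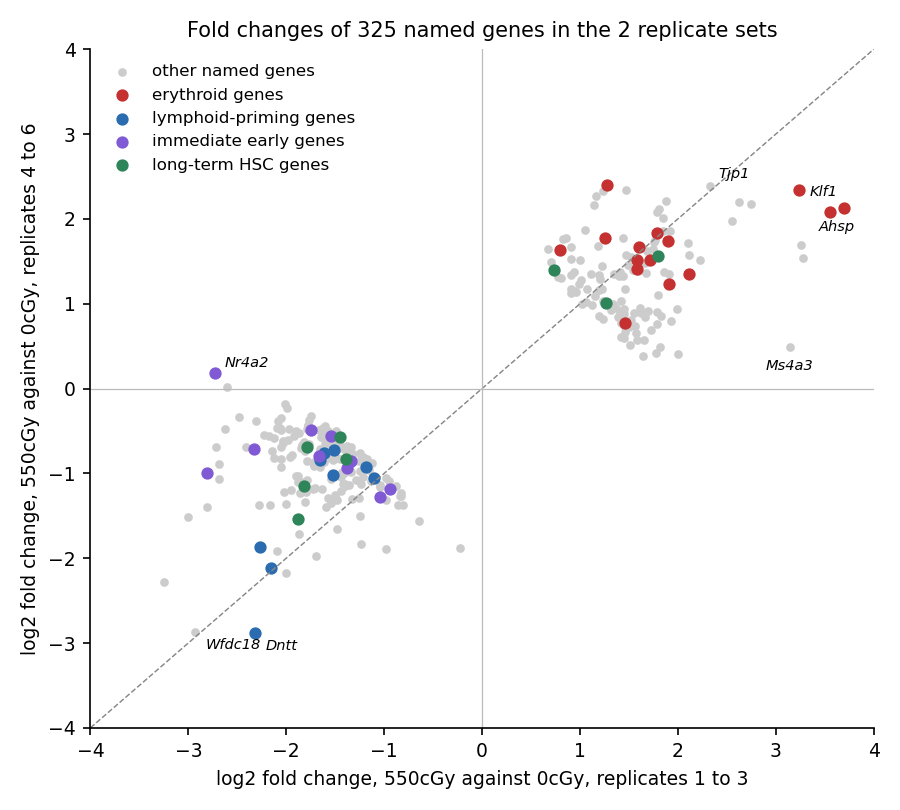
Log2 fold change of irradiated against non-irradiated arrays for the 325 named genes in replicates 1 to 3 (x axis) and in replicates 4 to 6 (y axis), with the members of 4 lists coloured and the line of equal change dashed. Erythroid genes lie above 0 and lymphoid-priming genes below 0 in both sets, and Nr4a2 and Ms4a3 lie at 0.18 and 0.49 in replicates 4 to 6.

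The other lists held few genes of the table. Among imprinted genes Grb10 rose, Ndn fell and Meg3 had a log2 change of -1.02 (adjusted p = 0.0762, or 0.00736 with the set term). That 3 of them passed when adjusted over the list alone was fixed by the selection of the table. Among receptor kinase and mTOR pathway genes Grb10 rose and Flt3 fell. The table held 1 gene each of granulocyte-monocyte priming (Ms4a3, 3.53-fold higher), homologous recombination (Rad52, 2.02-fold lower), the interferon response (Gbp2, 2.03-fold lower), glycolysis (the lactate transporter Slc16a1, 2.14-fold higher), homing (Robo4) and the BCL2 family (Bcl2l11, log2 change -1.57, adjusted p = 0.0991, or 0.0494 with the set term). It held 0 genes of the lists for end joining, MHC class II, ribosome biogenesis, the respiratory chain, cholesterol synthesis and the oxidative stress response. Of the markers of other bone marrow cells, Fcer1a and Il1rl1 of mast cells and basophils rose 2.14-fold and 2.02-fold. The table held 0 genes of the marker lists for mature neutrophils, B cells, T and NK cells, macrophages and dendritic cells, or stroma and endothelium. These lists do not cover all genes of such cells, and among others outside them Pdgfrb (2.44-fold and 3.60-fold in its probe sets), Cd86 (2.60-fold) and Emcn (2.02-fold) fell, Mpeg1 and Cd28 had adjusted p of 0.0522 and 0.109 at log2 changes of -1.06 and -1.02, and both T cell receptor gamma probe sets rose (2.90-fold and 3.26-fold). How many genes of these lists had a probe set is not known here.

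The probe sets of the authors' deposited table, which holds 178 higher and 276 lower ones, were found again from the log2 values. Of these, 451 were in the value table, and they were the same 451 that had a change of at least 2-fold and an unadjusted p under 0.05 in a recomputed one-way analysis of variance. The remaining 3 were control probe sets of Tfrc, the transferrin receptor, with ratios of 2.04, 2.15 and 2.41 at the 3' end, the middle and the 5' end in the authors' deposited table. After adjustment in limma, 410 of the 451 passed (90.9%), 156 higher and 254 lower. The other 41 had adjusted p up to 0.121. The direction was the same in both replicate sets for 449 of the 451. The selection on the pooled change, which is the mean of the changes in the 2 sets, favours this agreement. Across all probe sets the changes in the 2 sets correlated with r = 0.586. A further 2157 probe sets passed the adjusted threshold with changes below 2-fold and carry no name here.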

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

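The tests on the replicate sets and the globin probe sets in this part were chosen after the result was seen. The sets were chosen on these same arrays, so p-values for differences between them are descriptive.

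Of 130 groups of 6 arrays, 4 held an array far from the others by Dixon's criterion, where chance gives 6.5. Klf1 was 5.038 in control replicate 1 against 7.05 to 8.12 in the other controls. Hspa1b was 4.834 in control replicate 2 against 7.31 to 8.12. Gdf3 was 7.561 in control replicate 5 against 5.97 to 6.50. Plek was 9.456 in irradiated replicate 1 against 9.61 to 9.68. The rise of Mcm10 differed between the replicate sets, with 1.78 in replicates 1 to 3 and 0.76 in replicates 4 to 6 (difference -1.024, interaction adjusted p = 0.0308).

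Replicates 1 to 3 differed from replicates 4 to 6 in both groups. The difference between the sets in control arrays and that in irradiated arrays correlated across probe sets with r = 0.4002, the highest of 100 pairings of 3 and 3 arrays, the next being 0.336. The sets were chosen because they part along component 2 in both groups, so this r describes the split and tests no explanation. A technical batch shared by both groups and a difference between the animals cannot be told apart, because the labels name no batch.

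The immediate early genes of the authors' table were lower after irradiation. Each replicate set holds 3 arrays of each group, so a shift between the sets that both groups share cancels out of the pooled change. The list mean also differed by -0.7612 in replicates 4 to 6, where the pooled SD was 0.06. That value is no separate support, because the selection of the table on the pooled change favours a fall in both sets. Whether a weaker handling response in the irradiated arrays, shared by all members, contributes is left open. In replicates 4 to 6, 0 of 10 members lay above 0 by more than 2 SE, which decides nothing because the table was selected on these arrays for changes of at least 2-fold. Handling and irradiation cannot be told apart here, because no sorting times are given. The difference of the list's change between the sets had an exact two-sided p of 0.0150 (adjusted p = 0.0650 over 13 lists).

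The erythroid genes of the authors' table were higher after irradiation. As each replicate set holds 3 arrays of each group, a shift between the sets that both groups share cancels here too. The list mean differed by 1.694 in replicates 4 to 6, where the pooled SD was 0.35, but the selection of the table favours a rise in both sets. Erythroid cells carried along in varying number in the sorted fraction may contribute: within group and replicate set the 15 genes had a mean pairwise correlation of 0.6372, against a highest value of 0.335 in 10000 random lists of named genes. A varying share of erythroid-primed cells within the KSL gate would give the same correlation and stays open. The random lists drew on higher and lower genes alike, while these 15 genes were all higher. Genes regulated together could thus exceed them too, and the comparison does not single out carried-along cells. The sort for Kit, Sca-1 and absent lineage markers would remove mature erythroid cells. The 5 globin probe sets of the table were all higher, by 2.28-fold to 9.16-fold, which goes with erythroid cells carried along and with erythroid priming alike.

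The counts of called probe sets and of those changed at least 2-fold were compared with those of other splits. Of 100 splits of the 12 arrays, drawn from 462, only 1, the real one, reached 2567 called probe sets, and the highest other drawn gave 4. For calls of at least 2-fold the real value was 410 and the highest other drawn 4. A chance division of these arrays is thus an unlikely source of the counts. Chance differences between animals are not excluded, because the labels do not say that the arrays came from separate mice. Calls within the authors' table cannot be tested in this way, because the table was selected by the real grouping. The split of replicates 1 to 3 against 4 to 6, which was not among those drawn, called 577, of them 63 at least 2-fold.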

How the results depend on the processing

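The settings on replicate sets were chosen after the data were seen. With all 12 arrays and another filter, normalization, prior, weighting or block, 1276 to 1765 probe sets were higher and 1081 to 1430 lower, and 2095 to 2410 of 2567 calls were shared. At 2-fold and an unadjusted p under 0.05, 459 probe sets passed. This alternative both adds a fold threshold and drops the adjustment. Dropping the adjustment alone gave 6010 and adding the fold threshold alone gave 410, so the fold threshold lowered the count. Leaving out 1 array gave 740 to 1531 higher and 773 to 1303 lower probe sets, 128 to 190 and 200 to 298 at least 2-fold. It also gave 351 to 409 of the authors' probe sets, 47.7 to 56.2 on component 1 and a log2 change of 0.94 to 1.20 for the brightest Grb10 probe set. Which property of the arrays moved these counts was not tested. With the replicate set as a term 2099 were higher. Each set holds 3 arrays of each group, so this term leaves the log2 changes as they were, and the count moved through their errors. Replicates 1 to 3 alone gave 539 higher and 601 lower, 387 of the latter at least 2-fold, and replicates 4 to 6 alone 720, 738 and 132, with fewer arrays. Component 1 then differed by 71.8 and 50.2, where 3 against 3 arrays cannot pass. The brightest Grb10 probe set differed by 0.96 in replicates 1 to 3 (limma adjusted p = 0.128, range over alternatives 0.000711 to 0.128). The Grb10 probe set with the largest change passed in each set alone (adjusted p = 0.00961 and 0.00951), while the dimmest missed in replicates 1 to 3 (adjusted p = 0.116). Samples with the same number correlated in their deviations by 0.0106 to 0.286, so the numbers were not taken to pair them. With a replicate block 1451 probe sets were higher and 1350 lower, 167 and 258 at least 2-fold, and 419 of the authors' passed, while 2 of 6 controls correlated best with their own number. Among 1047 comparisons of 50 named genes other than Grb10 with an alternative, 0 reversed, 21 lost the call (8 without 1 array, for Vwf and Trp53inp1, and 13 within 1 replicate set) and 8 gained it, all for Cdkn1a. The filter on dim probe sets gave no value for 3 of these genes. List tests by camera or fry, means over the probe sets of a gene and the 3' to 5' covariate were not run, for want of gene names and control probe sets. Signal over background was not given, so its limit is unknown.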

Other observations

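All gene groups in this part were chosen after their values were seen, from the authors' table, so their directions are descriptions. Of 5 genes grouped here under iron uptake and transport, 4 rose. They were Slc40a1, the iron exporter ferroportin (3.39-fold, adjusted p = 0.0495), Abcb6 (2.37-fold, adjusted p = 0.0412), Steap3, a ferrireductase (2.34-fold), and Slc11a2, an iron importer (2.30-fold). Slc40a1, Abcb6 and Steap3 overlapped between the groups and missed the threshold in replicates 1 to 3 alone (adjusted p = 0.103, 0.194 and 0.0804). Of the probe sets of Tfrc the brightest had an adjusted p of 0.0596 and the other rose (2.08-fold, adjusted p = 0.0105). The metallothionein genes Mt1 and Mt2 were 5.31-fold and 7.06-fold higher, and the inducible Hsp70 genes Hspa1a and Hspa1b, near-identical copies whose probe sets can share signal, 3.62-fold and 5.50-fold. Of 4 genes of amino acid and folate-dependent synthesis, Mthfd2 (2.38-fold), Aldh18a1 (2.09-fold) and Asns (2.05-fold) rose, and Gpt2 had a log2 change of 1.26 (adjusted p = 0.0915). Of 8 genes of TGF-beta family signalling, the receptors Tgfbr2 (2.16-fold) and Acvr2a (2.16-fold), the inhibitors Smad7 (2.93-fold) and Skil (2.81-fold) and the latent TGF-beta binding protein Ltbp3 (3.67-fold) fell. The ligand Gdf3 (3.76-fold) and the co-receptor Tgfbr3 (2.21-fold) rose, and the probe sets of Ldlrad4 were lower by 2.07-fold in the brightest (adjusted p = 0.0599) and by 2.40-fold in the other (adjusted p = 0.00783). Socs2 rose (3.82-fold) while Socs3 fell (2.16-fold), as did the cytokine and growth factor genes Lif (4.30-fold), Vegfa (2.61-fold), Il18 (2.42-fold), Clcf1 (2.36-fold), Hbegf (2.27-fold) and Ebi3 (2.10-fold). The nuclear RNA Malat1 went from 11.94 ± 0.09 to 10.88 ± 0.25, and the RNA-binding protein genes Rbm39, Pabpc1, Luc7l2, Snrpd3 and Sfpq were 2.49-fold, 2.18-fold, 2.14-fold, 2.09-fold and 2.05-fold lower. The circadian genes Per1 and Per2 fell (2.35-fold and 2.00-fold). The immunoglobulin segment Iglv1 rose (2.90-fold, adjusted p = 0.0180), and Igk-V21 had a log2 change of 2.05 (adjusted p = 0.0555).

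The size of the change differed between the replicate sets for 30 probe sets at an interaction adjusted p under 0.05, 11 of them in the authors' table. The sets were chosen on these same arrays, so these p-values are descriptive. Ms4a3, a gene of granulocyte-monocyte progenitors, differed by 3.15 in replicates 1 to 3 and by 0.49 in replicates 4 to 6 (interaction adjusted p = 0.00503). Its control arrays stood at 7.50 and 9.85 in these sets and its irradiated arrays at 10.65 and 10.34. For Smad7 the controls stood at 10.15 and 10.10 and the irradiated arrays at 7.52 and 9.62 (interaction adjusted p = 0.0308), and for Per1 at 9.41 and 9.17 against 7.33 and 8.78 (interaction adjusted p = 0.0261).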
